A study of Rattus norvegicus with 18 samples.

How the data were processed

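Rat cortical collecting ducts, the kidney tubule segments that adjust the final sodium, potassium, acid and water content of urine, were microdissected from male Sprague-Dawley animals 3 h after an intraperitoneal injection of lipopolysaccharide (LPS), the bacterial cell wall component, or of saline vehicle. Per the labels, total RNA was copied into cDNA with an ultra-low-input template-switching kit, amplified by PCR and made into libraries by tagmentation. The labels give 2 groups, 3 numbered samples in each and 3 libraries per numbered sample, 18 libraries in all.

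The deposited table holds TPM, a transcript abundance corrected for length, for 32883 Ensembl genes with a symbol and an annotation line, 1 column per library. Per the submitters' processing notes, the tools were STAR 2.7.9a and RSEM 1.3.3 and the genome build was Rnor_6.0. The annotation release and any filter are not given in the sources used here. TPM divides by transcript length and scales each library to the same total, and it keeps no read number, so the sequencing depth of each library is unknown and no counting interval is given. RSEM shares reads between near-identical transcripts by estimate, so values of close paralogs such as the RT1 genes and the metallothioneins are uncertain. Of the tested rows, 244 share a symbol with another row, and 384 rows of the table carry no symbol. No coordinates are given because no annotation of the files' build was used here.

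Column names begin with N or L, and N was read as the normal saline vehicle and L as LPS, with the numbers read as sample and library. No columns of other samples were present (0 columns), and 0 libraries were identical to another.

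The unit of replication was the numbered sample. Values were log2(TPM + 1), averaged over the 3 libraries of a sample. Genes with a mean of at least 1 TPM over all libraries were tested, 12393 in number, and 20490 were not. A gene near 0 in Vehicle passes this filter only if it is higher in LPS, which raises the share of tested list members that rise. LPS was compared with Vehicle by limma 3.58.1 in R 4.3.3 (empirical Bayes with a variance trend, two-sided moderated test, Benjamini-Hochberg adjustment), with the sample number as a block because the design text calls the samples paired. A gene was called higher or lower at an adjusted p under 0.05. The fit leaves 2 residual degrees of freedom and a prior worth 4.97. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low values. Nothing in the labels says that the numbered samples came from separate animals or what a pair shared, so p-values measure the spread between these samples.

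Same-numbered samples correlated weakly in their deviations from the group means (r = 0.062, -0.017 and 0.069 across genes), so the pairing rests on the design text. The 29 gene lists (19 pathway lists and 10 lists of markers of cell types) were fixed before the data were examined. Lists with at least 3 tested genes, 26 in number, were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry. Camera compares the genes of a list with the other tested genes, so its direction is relative to them. Of 643 list members, 16 were not analysed here, Gapdh and Pecam1 among them, because no row of the table had their symbol. The genes named were the 12 largest rises and 12 largest falls among called genes moved the same way in the 3 pairs with at least 5 TPM in the higher group, a fixed set of transport and response genes, the members of each pathway list with the smallest p, and the most abundant members of each marker list. Other genes named were chosen after their values were seen. Some genes that the rule names are not reported here.

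Alternatives were the fit without the block, all 18 libraries with an estimated correlation, another summary over libraries, other pseudocounts, other filters, other scalings, other variance models and leaving out each sample number. The set without libraries that stood apart, the gene families and all tests of explanations were added after the data were seen. The test of RNA from other cells is a revised one: an earlier comparison between LPS samples and an earlier slope pooled over lists were replaced after their results were seen. Earlier tests of the falls left out the genes called higher, and an earlier test of a mixture in LPS 1 rested on the spread between its libraries; these too were replaced after their results were seen. The fitting code was tested on simulated data with 200 changed genes, 50 at each of 4 sizes, in a fit of 11999 genes. At 1.5-fold 2% of the changed genes were called, at 2-fold 42%, at 4-fold 90% and at 8-fold 96%. Of 11799 unchanged genes 12 were called. The simulation took its spread from the Vehicle samples and gave same-numbered samples a shared deviation. In the data the median SD was 0.254 (log2) between LPS samples and 0.169 between Vehicle samples, and same-numbered samples correlated weakly. The rates of detection can therefore be too high for this comparison.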

Results

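RNA was measured in cortical collecting ducts dissected from rat kidneys 3 h after injection of LPS or saline, to ask which transcripts differ early after LPS. Each group held 3 numbered samples of 3 libraries. A library listed between 11399 and 12704 genes at 1 TPM or more, with a mean of 12200 ± 293 genes in Vehicle and 11630 ± 69.8 in LPS (SD, n = 3). Mitochondrially encoded transcripts made up 8.77% ± 0.606 of TPM in Vehicle and 8.16% ± 0.178 in LPS (SD, n = 3). The depth is unknown. Library pairs of the same sample had a median Pearson correlation of 0.97 across genes, against 0.872 for a Vehicle and an LPS library; genes are not independent replicates. The first principal component held 56.1% of the variance. LPS 1 lay between Vehicle and the other LPS samples on it.

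**Figure D1:**
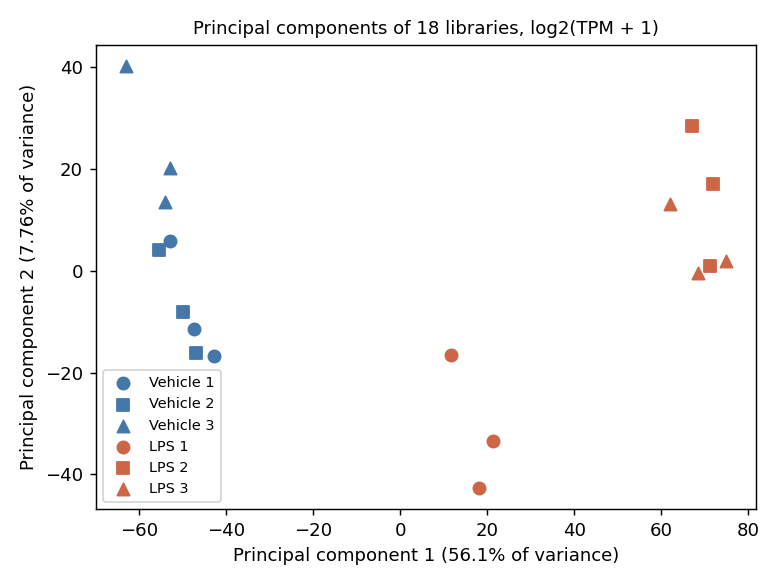
Principal components 1 and 2 (arbitrary units) of log2(TPM + 1) for 18 libraries, coloured by group and shaped by sample number, each point a library. The libraries of LPS 1 lie at 11.6 to 21.2 on the first axis, those of LPS 2 and LPS 3 at 62.1 to 74.8 and the Vehicle libraries at -63.1 to -42.9.

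After LPS, collecting ducts carried far more chemokine and interferon-stimulated RNA. Cxcl10 (ENSRNOG00000022256), which encodes a chemokine that draws T cells, stood at 8.88 ± 3.86 TPM in Vehicle and 9792 ± 6210 TPM in LPS (SD, n = 3). Ifit3 (ENSRNOG00000022839), an antiviral interferon-stimulated gene, went from 3.19 ± 1.40 to 4807 ± 2360 TPM, and Lcn2 (ENSRNOG00000013973), which encodes the iron-sequestering lipocalin, from 1.91 ± 0.686 to 572 ± 426 TPM. Avpr2 (ENSRNOG00000059862), the vasopressin V2 receptor gene, was lower, at 692 ± 47.2 TPM in Vehicle and 174 ± 152 TPM in LPS, and Kcnj1 (ENSRNOG00000059005), the gene of the potassium channel ROMK, fell from 1155 ± 119 to 288 ± 40.4 TPM.

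With limma, 889 genes were higher and 2757 lower with LPS, 29.4% of those tested. Of these, 884 and 2755 moved the same way in the 3 pairs, and 678 and 1269 moved at least 2-fold. The median log2 change of all tested genes was -0.38. With each library scaled by its median ratio the split was 821 higher and 460 lower, with a median of -0.02, and with quantile normalization it was 809 and 579, so the calls of changes near the median depend on the scaling. The scaled fits also had a weaker prior, with 2.74 and 2.88 degrees of freedom against 4.97, and some genes lost their call there with a change about as large. The counts fell to 419 and 296 without replicate 2, to 581 and 1146 without the 3 libraries that stood apart, and to 0 and 0 by limma without replicate 3 (738 and 1463 at an unadjusted p under 0.05) and with the median of the libraries in place of their mean (1019 and 4167 unadjusted). Without a filter on low values the counts were 18 and 2.

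By the rule fixed for naming, the largest rises were in Ifit3, Cxcl10, Cxcl11, Rsad2, Ifit2, Ubd, Cd274, Ccl20, Lcn2, Mx1, Oasl and MGC108823. Ifit3 rose by 10.16 (log2, SE 0.408, limma adjusted p = 0.000113) and MGC108823 by 6.74 (SE 0.36, adjusted p = 0.000267). Cd274 encodes the checkpoint ligand PD-L1, and it went from 0.709 ± 0.188 to 487 ± 376 TPM (SD, n = 3). Ccl20 rose by 7.43 (SE 0.241). The largest falls were in Prr35, Rab3a, A4galt, Cavin2, Klf15, Cdca7l, Hmx2, Dbp, Usp2, Ddit4l2, Smad6 and Grem1. Prr35 fell by 4.61 on the log2 scale (SE 0.511, limma adjusted p = 0.00273), and Grem1, an antagonist of bone morphogenetic proteins, by 2.97 (SE 0.519, adjusted p = 0.0128), or 2.58 with adjusted p = 0.0554 under median-ratio scaling and 2.86 with adjusted p = 0.0435 with quantile normalization. A4galt, a glycosphingolipid galactosyltransferase gene, stood at 450 ± 6.89 TPM in Vehicle and 56.4 ± 68.3 TPM in LPS. Klf15, Dbp and Usp2 are known as glucocorticoid or clock responsive genes.

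The interferon-stimulated list rose almost as a whole, with 36 of 37 tested members higher (36 adjusted over the list alone) and a mean log2 change of 4.69. Isg15 went from 26.1 ± 16.6 to 1912 ± 504 TPM and Igtp, an immunity-related GTPase gene, from 26.8 ± 3.62 to 1454 ± 724 TPM (SD, n = 3). Ifit1 was not called, with 0.153 TPM in LPS 1, 2.72 TPM in LPS 2 and 1586 TPM in LPS 3. The list's camera test gave adjusted p = 2.9e-52, and adjusted p = 0.313 with an estimated correlation. Antigen presentation genes followed, with 20 of 26 higher (21 adjusted over the list alone). Tap1, a peptide transporter gene, rose by 5.83 (SE 0.354), and the immunoproteasome subunit genes Psmb8 and Psmb9 by 4.80 and 4.01. For that list camera gave adjusted p = 8.92e-25 and adjusted p = 0.258 with an estimated correlation.

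Of the cytokine and chemokine list, 22 of 25 tested members rose (23 adjusted over the list alone), with a mean of 3.75 and a median of 3.76. The list holds 37 members, and those near 0 in both groups were filtered out. Without the filter 36 members had a mean of 2.69 and a median of 1.67. Ccl2 rose by 6.45 (SE 0.383), Cxcl1 by 5.22 (SE 0.363) and Cxcl16 by 3.85 (SE 0.222). Tnf was listed at 0 in both groups, and Il15 stood at 11.4 TPM in Vehicle and 13.8 TPM in LPS. The camera test of the list gave adjusted p = 1.86e-31, and adjusted p = 0.258 with an estimated correlation. NF-kappaB targets, the direct transcriptional response to many bacterial signals, rose in 23 of 25 tested members (24 adjusted over the list alone). Birc3, an inhibitor of apoptosis gene, rose by 6.04 (SE 0.183), Bcl3 by 6.46 (SE 0.214), Relb by 4.38 (SE 0.187) and Nfkbia by 2.33 (SE 0.399). For these targets camera gave adjusted p = 3.06e-33, and adjusted p = 0.175 with an estimated correlation. Markers of monocytes and macrophages also rose in 4 of 13 tested members (6 adjusted over the list alone) and fell in 1, with a list mean of 0.53 and camera adjusted p = 2.37e-05 (adjusted p = 0.326 with an estimated correlation). Among them Fcer1g went from 17.3 ± 5.78 to 49.4 ± 15.8 TPM and Lyz2 stood at 114 ± 48.0 and 152 ± 88.1 TPM (SD, n = 3). Within an LPS sample, libraries with higher macrophage markers had higher cytokine levels, with a log2 slope of 0.746 ± 0.154 (SE, 9 libraries), or 0.432 ± 0.126 without LPS 3 library 3.

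**Figure D2:**
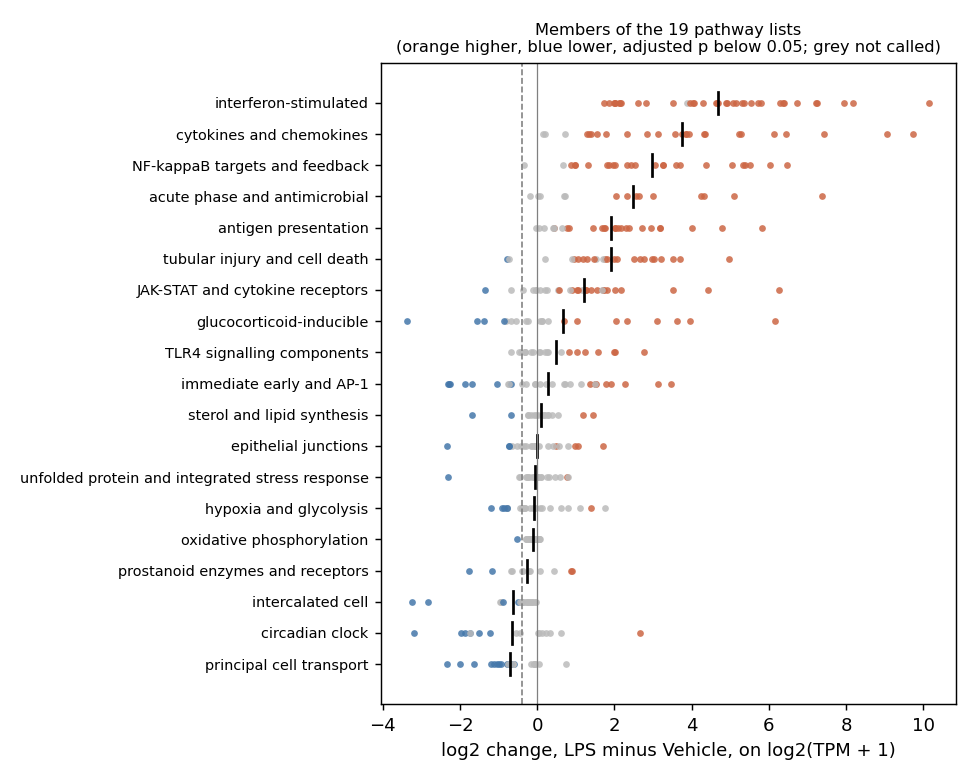
Log2 change, LPS minus Vehicle on log2(TPM + 1), of each tested member of the 19 pathway lists, with orange and blue points called higher and lower by limma, grey points not called, black bars list means and the dashed line the median of all tested genes at -0.38. The interferon-stimulated list has the highest mean at 4.69 and the principal cell list the lowest at -0.72.

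The acute phase list had 14 tested members out of 30, of which 9 rose (9 adjusted over the list alone). Tested members had a mean log2 change of 2.49 and a median of 2.44. Without the filter, which drops members near 0 in both groups, 27 members had a mean of 1.48 and a median of 0.664. Cfb, a complement gene, rose by 5.09 (SE 0.289), C1r by 3.01 and Steap4 by 4.25. Defb1, a defensin gene, stood at 4188 and 3685 TPM. The list had a camera adjusted p = 2.03e-11 and adjusted p = 0.313 with an estimated correlation. Of the JAK-STAT list 16 of 29 rose and 1 fell (18 and 2 adjusted over the list alone). Socs1, a feedback inhibitor gene, rose by 6.25 (SE 0.68), Osmr by 4.43 and Tnfrsf1a by 2.02, while Pim3 fell from 232 to 87.9 TPM. By camera it had adjusted p = 2.41e-13 and adjusted p = 0.396 with an estimated correlation. The tubular injury and cell death list had 18 of 24 higher and 1 lower (19 and 1 adjusted over the list alone), Tnfrsf12a by 3.04, Sox9 by 2.77, Casp4 by 3.70 and Ripk3 by 3.51. Camera gave adjusted p = 1e-18 and adjusted p = 0.313 with an estimated correlation. Havcr1, which encodes kidney injury molecule 1, stood at 0.0267 and 0.0533 TPM. The TLR4 signalling list had 7 of 21 higher (8 higher and 1 lower adjusted over the list alone), with Tlr2 up by 2.78 (SE 0.22), Myd88 by 2.02 and Irak2 by 1.58, camera adjusted p = 2.37e-05 and adjusted p = 0.315 with an estimated correlation. Tlr4, the receptor gene for LPS, was below the filter at 0.453 ± 0.144 TPM in Vehicle and 1.09 ± 0.0934 TPM in LPS (SD, n = 3).

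Genes of principal cells, the water and sodium handling cells of the duct, were lower or not called. Of 22 tested members 12 fell and 0 rose (13 fell and 1 rose adjusted over the list alone), with a mean log2 change of -0.72. Aqp2 (ENSRNOG00000054378), the vasopressin-regulated water channel gene, stood at 5961 ± 551 TPM in Vehicle and 4012 ± 1100 TPM in LPS (SD, n = 3) and fell by 0.60 (SE 0.126, limma adjusted p = 0.0207), Aqp3 fell by 0.76, Aqp4 by 1.00, Hsd11b2 by 0.78 and Avpr2 by 2.33. Nr3c2 (ENSRNOG00000034007), the mineralocorticoid receptor gene, fell by 1.65 (SE 0.198, adjusted p = 0.00368) and Kcnj1 by 2.00 (SE 0.122, adjusted p = 0.000389). Under median-ratio scaling the list had 2 lower and a mean of -0.34, and Kcnj1 and Nr3c2 were still called, at -1.59 and -1.26, but Aqp2, Aqp3, Aqp4, Avpr2 and Hsd11b2 were not, at -0.19, -0.36, -0.60, -1.93 and -0.38. With quantile normalization 7 were lower with a list mean of -0.65, and of these 5 genes Aqp2 alone lost its call, at -0.66 with adjusted p = 0.0524. The sodium channel genes Scnn1a, Scnn1b and Scnn1g had log2 changes of -0.62, -0.07 and -0.07 with SE of 0.28, 0.141 and 0.14 and were not called. Camera gave adjusted p = 0.033 for the list, adjusted p = 0.0647 without the replicate block and adjusted p = 0.617 with an estimated correlation, and from 0.000733 to 0.617 over 17 alternatives.

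Genes of intercalated cells, the acid and base secreting cells, fell in 5 of 21 tested members (4 adjusted over the list alone), with camera adjusted p = 0.0636. Of all 12393 tested genes 2757 fell, which is a similar share. The list median of -0.364 lay close to the median of -0.382 over all tested genes. Oxgr1, a receptor gene, fell by 2.82 (SE 0.488, limma adjusted p = 0.0124), Hmx2 by 3.25, Ca12 by 0.90 and Atp6v1c2 by 0.49. Under median-ratio scaling none of the 4 was called, at -2.43, -2.85, -0.49 and -0.08. There the list mean was -0.226 and camera gave direction up with adjusted p = 0.797. With quantile normalization all 4 were called, at -2.62, -3.17, -1.01 and -0.57, and camera gave direction down with adjusted p = 0.000259. Foxi1, Slc4a1 and Slc26a4 were not called. Markers of distal convoluted and connecting tubule, the segment before the collecting duct, were lower in 4 of 9 tested members (6 adjusted over the list alone), Calb1, Tmem52b, Wnk4 and Trpm6, with a list mean of -0.98 and camera adjusted p = 0.0833. Under either scaling 1 of the 9 was lower, and Calb1 was not called, at -2.02 with median-ratio scaling and -2.30 with quantile normalization. Camera called the list lower in 4 of 17 alternatives, with adjusted p from 0.0202 to 0.434 over the 17. It gave adjusted p = 0.0493 with median-ratio scaling and 0.0626 with quantile normalization. Over all 11 markers of the list, untested ones included, the mean level differed by -1.19, -0.558 and -0.665 in the 3 pairs. Calb1 stood at 1712 ± 2800 TPM in Vehicle and 97.6 ± 99.0 TPM in LPS (SD, n = 3), with 4943 TPM in Vehicle 1 against 64.8 and 129 TPM in Vehicle 2 and 3.

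**Figure D3:**
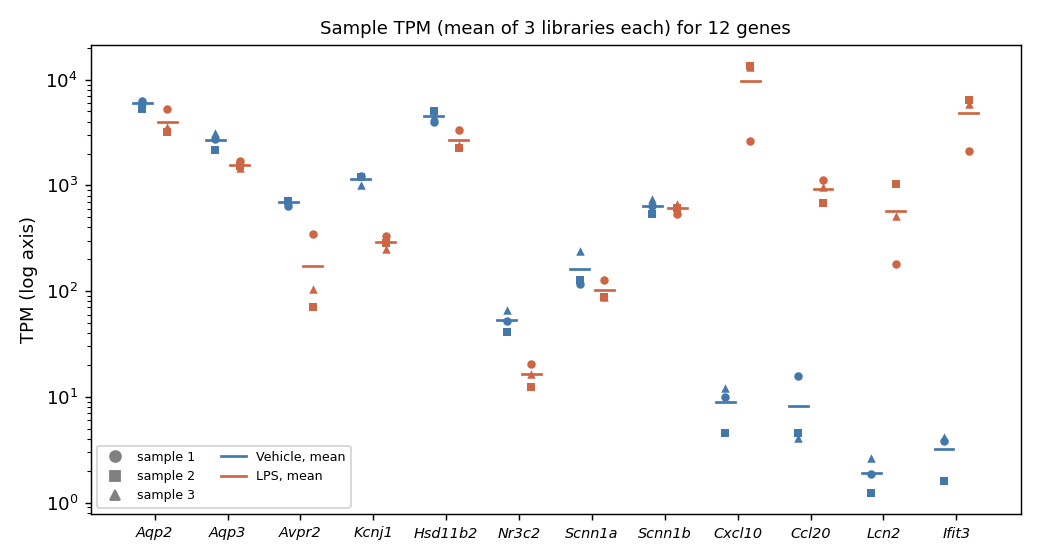
TPM on a log axis for 12 genes in each numbered sample (mean of 3 libraries; circle, square and triangle for samples 1, 2 and 3), with a bar at the group mean, blue for Vehicle and orange for LPS. Avpr2 lies at 692 TPM on average in Vehicle and 174 TPM in LPS, and Scnn1b at 637 and 606 TPM.

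Immediate early genes went both ways, with 8 of 29 higher and 7 lower (9 and 8 adjusted over the list alone), but 2 and 1 under either median-ratio scaling or quantile normalization, where camera gave adjusted p = 0.131 and 0.139. Nr4a1 fell by 2.31 (SE 0.229) and Fosb by 1.86 (SE 0.288), or 1.52 and 1.49 under the 2 scalings with adjusted p = 0.0554 in each, while Maff rose by 2.28 and Dusp6 by 1.92. Camera gave adjusted p = 0.00207 for a mean of 0.28, and adjusted p = 0.617 with an estimated correlation. Of the glucocorticoid-inducible list 8 of 21 rose and 4 fell (8 and 4 adjusted over the list alone). The members that rose included Cebpd, Angptl4 and the metallothionein genes Mt1 and Mt2A, which cytokines and metals are also known to induce. Mt2A went from 931.6 ± 148 to 12400 ± 5470 TPM (SD, n = 3), and Klf15 and Tsc22d3 fell. Under either scaling 1 of this list was lower. Camera gave adjusted p = 0.000126 and adjusted p = 0.313 with an estimated correlation. Clock genes had 6 of 16 lower and 1 higher (7 and 1 adjusted over the list alone), with Dbp, Cry2 and Tef down by 3.20, 1.75 and 1.98 and Nfil3, a repressor of the same promoter elements, up by 2.67. Under either scaling 2 were lower, and Tef was not called, at -1.64 and -1.63. Camera gave adjusted p = 0.952 for that list.

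The remaining lists were mostly not called gene by gene. Camera sets a list against the other genes, and the median change of all tested genes was -0.38. A camera direction up with a mean near 0 is therefore relative to those genes and is not a rise. Some genes lost their call under scaling. With median-ratio scaling and quantile normalization Hspa5 stood at 1.19 and 0.66, Lss at 1.57 and 1.44, Scd2 at -1.33 and -1.36, Pla2g4a at -0.81 and -0.80 and Acly at -0.29 and -0.36, without a call in either. Ndufs1 and Cldn8 were not called with median-ratio scaling, at -0.11 and -0.33, and were called with quantile normalization, at -0.58 and -0.87. Oxidative phosphorylation had 28 of 29 members not called, with Ndufs1 at -0.51 the 1 that fell (0 adjusted over the list alone). Its mean was -0.10 and its camera direction up, with adjusted p = 0.417. The scalings called it in opposite directions, up with median-ratio scaling (mean 0.30, adjusted p = 0.000164) and down with quantile normalization (mean -0.23, adjusted p = 0.00558). The hypoxia and glycolysis list had 1 higher and 5 lower of 24 (4 and 6 adjusted over the list alone), with Slc2a1 at -1.19 (SE 0.208), Pdk1 at -0.87, Hif1a at -0.78 and Hk1 at -0.92. Under either scaling 1 member was called by limma, a lower one, and Pdk1, Hif1a and Hk1 were not called, at -0.47, -0.38 and -0.52 with median-ratio scaling and -0.58, -0.70 and -0.70 with quantile normalization. Its mean was -0.07 and its camera direction up, with adjusted p = 0.34. Of the prostanoid list, Ptges and Ptger3 rose by 0.91 and 0.87 and Ptger1 and Pla2g4a fell by 1.76 and 1.17 (2 and 3 adjusted over the list alone). Its mean was -0.26 and its camera direction up, with adjusted p = 0.539. The unfolded protein list had Hspa5 higher at 0.78 and Sesn2 lower at -2.32 among 23 (0 and 1 adjusted over the list alone), a mean of -0.05, camera direction up with adjusted p = 0.0432, and adjusted p = 0.48 with an estimated correlation. Of the junction list 4 of 23 rose and 3 fell (5 and 3 adjusted over the list alone), among them Krt8 and Marveld3 at 1.05 and 0.97 and Cgn and Cldn8 at -2.33 and -0.74. Its mean was -0.01, its camera direction up with adjusted p = 0.0277, and adjusted p = 0.436 with an estimated correlation. The sterol list had 2 of 17 higher and 2 lower (2 and 1 adjusted over the list alone), among them Lss at 1.18, Scd2 at -1.69 and Acly at -0.68, with camera adjusted p = 0.0063 and adjusted p = 0.478 with an estimated correlation.

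By limma no member was called, over all genes or adjusted over the list alone, of 10 tested proximal tubule markers, 6 thick ascending limb markers, 5 red cell markers or 2 fibroblast and mural markers. Among these, Cldn19 and Dcn had unadjusted p of 0.0154 and 0.039 by limma. Camera gave adjusted p of 0.19, 0.117 and 0.18 for the proximal tubule, thick ascending limb and red cell markers, the first with a mean of -0.14 and a direction up. Of 11 tested endothelial markers Esam, Flt1 and Sele rose and Egfl7 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.088), and Plvap stood at 36.7 ± 22.5 and 34.1 ± 16.7 TPM (SD, n = 3). Of the neutrophil markers S100a8 and S100a9 rose (2 adjusted over the list alone) and had changes of 1.80 and 1.94 with median-ratio scaling and 1.80 and 1.94 with quantile normalization, without a call in either. S100a8 was listed at 0 in Vehicle and stood at 2.42 TPM in LPS 1, 0.373 TPM in LPS 2 and 30.8 TPM in LPS 3, where it reached 86.9 TPM in library 3. Of the lymphocyte markers 1 of 3 rose, Gzmb (1 adjusted over the list alone), with a list mean of 0.29, a median of -0.09 and camera adjusted p = 0.185. Of the podocyte markers Synpo rose (1 adjusted over the list alone). By fry, 2 of the 26 lists tested had an FDR under 0.05, the NF-kappaB list at 0.026 and the cytokine list at 0.0408, and 0 lists were called by camera with an estimated correlation, where 15 were with the preset value. The estimated form has little power, so a list it did not call was not shown to be unchanged. The preset 0.01 in turn lies below the 0.794 estimated for the interferon-stimulated list, so its p-values can be too small. With the preset value, other splits of the 6 samples into 3 and 3 gave from 13 to 18 called lists. Those splits keep part of the LPS difference, so these counts are not a rate expected by chance.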

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

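Apart from the search for libraries that stood apart, the tests below were chosen only after the result was seen, and the tests for the falls, for LPS 1 and for RNA from other cells were revised after earlier forms of them had been seen. In 28 groups of 9 libraries, 3 libraries stood apart by Dixon's ratio, where chance gives about 1 in 20. Thick ascending limb markers in LPS 2 library 1 had a mean of 3.268 (log2), against 1.506 to 2.075 in the other LPS libraries. Neutrophil markers in LPS 3 library 3 had a mean of 1.734, against 0.16 to 0.6296. Fibroblast and mural markers in Vehicle 3 library 1 had a mean of 1.62, against 0.9259 to 1.153. Without these 3 libraries, a choice made after seeing the data, 581 genes were higher and 1146 lower.

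The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3646 called genes, as 1 of the 10, and the highest other split gave 0. For the lists called by camera with the preset correlation, 7 of the 10 splits gave as many as the real split's 15, the highest other split giving 18, again too few splits for a share under 0.05. The 3 other splits that part the 3 pairs gave 0 genes each and 16, 13 and 18 lists. Each other split has both treatments in each group, so part of the LPS difference stays in its comparison and part in its residual spread. Neither the genes nor the lists called in those splits therefore give a rate expected by chance.

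More genes were lower than higher with LPS, a pattern for which closure of the TPM scale and dropout of rare transcripts were weighed. Genes called higher held 5.04% ± 0.184 of TPM in Vehicle and 17.3% ± 5.42 in LPS (SD, n = 3), which alone would lower the other genes by a mean of -0.202 (log2), while the medians of all 4269 tested genes at 10 to 50 TPM (level over both groups) had a mean over the pairs of -0.436. That is -0.234 from the predicted shift (SD 0.134 over the pairs, with -0.14, -0.175 and -0.387 in the 3 pairs), which argues against closure by the genes called higher as the whole cause. The predicted shift leaves out abundant genes that rose without a call, so closure by those genes is not excluded. All 3627 tested genes at 20 to 100 TPM, above 0 in 99.95% of values, had medians with a mean over the pairs of -0.363 (SD 0.18), which argues against dropout as the whole cause. The median change of all tested genes was -0.482 at 10 to 20 TPM and -0.0305 above 300 TPM. Closure by abundant genes without a call, a difference in library complexity or amplification between groups and a broad fall of moderately expressed transcripts after LPS stay open. None of them was tested.

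LPS 1 responded less than the other LPS samples, with 591 and 564 genes at least 2-fold higher and lower in its pair against 1070 and 2029 in pair 2 and 903 and 2928 in pair 3. Against the other LPS samples, its median share of the way from Vehicle was 0.324 over 266 risen genes, with an upper quartile of 0.462, and 0.671 over 137 fallen genes. A mixture with Vehicle RNA at the share of 0.538 that the upper quartile needs could not take a gene below that share of its Vehicle level. In all 3 libraries of LPS 1, 45 of the 137 fallen genes (32.8%) lay below it. For those genes this argues against such a mixture as the whole cause. The percentage lay between the limits set for the test, so a mixture as part of the cause was not decided. For an earlier stage in LPS 1, NF-kappaB targets stood at a median share of 0.757 and interferon-stimulated genes at 0.376, and the difference taken in each library had a mean of 0.367. LPS 1 is 1 sample, and the spread between its own libraries does not show the spread between samples. A mixture as part of the cause, an earlier stage and a smaller exposure therefore cannot be told apart.

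The rise of cytokines and interferon-stimulated genes was weighed against RNA from cells other than duct cells, whose markers were fixed before the data were examined. If such cells were the source, libraries of 1 LPS sample with more of their markers would hold more of the response. A log2 slope of 1 was taken as what a source would give. That value assumes that members near 0 dampen the means of markers and response alike. The means covered whole lists, untested members included. The members of each marker list, parted into equal groups, predicted each other with slopes of 0.993 and 0.99, which cannot show unequal dampening. Of the marker lists 13 of 18 and 11 of 16 genes were tested; Lyz2 stood at 152 TPM and Plvap at 34.1 TPM in LPS. Interferon-stimulated genes had slopes of 0.277 ± 0.154 on monocyte and macrophage markers and 0.29 ± 0.149 on endothelial markers (SE, 9 libraries). With all 9 libraries and a slope of 1 as the yardstick, this argues against either as the whole source. Without LPS 3 library 3 the slopes were 0.256 ± 0.25 and 0.358 ± 0.294 (SE). With so few libraries that endothelial slope does not exclude 1, so the case against endothelial cells rests on that library. Cytokines and chemokines had slopes of 0.746 ± 0.154 and 0.762 ± 0.135, and 0.432 and 0.463 without LPS 3 library 3, so for them the source cannot be told apart because 1 library decides. Over the 25 tested members, single-gene slopes on macrophage markers ran from -0.903 for Ccl20 to 3.34 for Cxcl3. The single genes given here were chosen after the values were seen. Ccl4, Ccl5 and Il1b had slopes of 1.92 ± 0.679, 1.81 ± 0.389 and 1.93 ± 0.931 (SE). Without LPS 3 library 3 these were 1.72 ± 1.09, 2.15 ± 0.586 and 2.12 ± 1.51. Cxcl1 and Ccl2 had slopes of 2.18 ± 0.302 and 1.04 ± 0.305 (SE), or 1.8 ± 0.416 and 0.885 ± 0.484 without it. Cxcl10, Cxcl11 and Ccl20 had slopes of 0.277 ± 0.117, 0.138 ± 0.202 and -0.903 ± 0.366 (SE), or 0.0906 ± 0.141, -0.0505 ± 0.301 and -0.218 ± 0.361 without it.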

How the results depend on the processing

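The alternative without the 3 libraries that stood apart was chosen after the data were seen; the others were fixed before. Main counts were 889 higher and 2757 lower. With the 18 libraries and an estimated correlation of 0.45 they were 1189 and 5295, with the median of libraries 0 and 0, without a filter 18 and 2 of 23716 genes, with median-ratio scaling 821 and 460, with quantile normalization 809 and 579, and without the libraries that stood apart 581 and 1146. Leaving out a replicate gave from 0 to 1004 higher and from 0 to 3595 lower. Without replicate 3 limma called 0 genes (738 higher and 1463 lower at an unadjusted p under 0.05), and with the median of libraries 0 (1019 and 4167 unadjusted); prior degrees of freedom were 2.51 and 1.61, against 4.97 as reported. The cause was not tested. Without the replicate block 912 were higher and 3624 lower, sharing 824 and 2619 with the paired fit.

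The scalings moved the median log2 change of all tested genes, from -0.382 to -0.0205 with median-ratio scaling and to -0.124 with quantile normalization. A list mean near 0 can change sign by such a shift alone. No other cause was tested. List means that changed sign with a call on either side were these. Epithelial junctions: 0.026 with a pseudocount of 5, 0.375 with median-ratio scaling and 0.162 with quantile normalization. Oxidative phosphorylation: 0.301 with median-ratio scaling. Unfolded protein response: 0.346 with median-ratio scaling and 0.0401 with quantile normalization. For each of these means the camera direction was up, as in the reported fit. Leaving out a replicate gave means from -0.145 to 0.74 for immediate early genes, -0.185 to 0.00443 for oxidative phosphorylation, -0.0897 to 0.00731 for the unfolded protein list, -0.0493 to 0.0578 for junctions and -0.926 to 0.777 for proximal tubule markers. The prostanoid, hypoxia, thick ascending limb and red cell lists also had means of either sign, from -0.337 to 0.108, -0.116 to 0.301, -0.274 to 0.491 and -0.632 to 0.792, without a call in the reported test. The NF-kappaB, cytokine, interferon-stimulated, acute phase, JAK-STAT, glucocorticoid-inducible, TLR4, injury, antigen presentation and macrophage lists kept their direction and call in 16 of 17 alternatives, the exception being the estimated correlation. No named gene that was called changed sign. With median-ratio scaling 26 named genes lost their call, without a filter 93, and with the median of libraries or without replicate 3, 101 did, which is each of those called. Depth is unknown, so precision at low TPM is not given.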

Other observations

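Gene families were grouped by symbol after the data were seen, as were their tests. All 7 tested guanylate-binding and immunity-related GTPase genes, which restrict microbes inside cells, rose, with a median log2 change of 5.29. Gbp2 went from 1.14 to 253 TPM and Irgm from 9.56 to 664 TPM. Of 48 proteasome subunit genes 9 rose and 0 fell, with Psmb10 higher by 3.18 and Psme2 by 1.45; the family median was -0.09, and 0.31 under median-ratio scaling. Tripartite motif genes went both ways, with 5 of 30 higher and 10 lower, against 4 and 1 with median-ratio scaling and 5 and 2 with quantile normalization, and their mean of -0.08 became 0.26 and 0.22 there. Trim25, which acts in the RIG-I pathway, rose by 3.27 (SE 0.373) and Trim21 by 2.83 (SE 0.307). Cytosolic ribosomal protein genes, 86 tested, had a lowest adjusted p of 0.0672 and a median of 0.03, and 0.44 under median-ratio scaling, where 4 rose.

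Of all 12393 tested genes 2757 fell and 889 rose, and the counts of a family are to be read against those shares. Among 224 tested zinc finger genes of the Zfp and Znf symbols 79 fell and 2 rose, with a median of -0.58. Under median-ratio scaling 14 fell and 4 rose, with a median of -0.27. With quantile normalization 17 fell and 4 rose, with a median of -0.24. Of 25 homeobox genes 9 fell and 2 rose, against 3 and 1 under median-ratio scaling and 5 and 1 with quantile normalization. Emx2 went from 13.2 to 2.54 TPM and Lhx1 from 32.5 to 6.59 TPM, while Hoxb2 rose by 1.19 (SE 0.234). Of 14 Wnt pathway genes 7 fell, with Wnt7b at -1.93 and Fzd1 at -1.25, but with median-ratio scaling limma called 0 lower (6 at an unadjusted p under 0.05) and with quantile normalization 1. Of 16 potassium channel genes 4 fell and 2 rose, against 2 and 1 under either scaling. Kcnj13 fell by 2.77 (SE 0.321) and Kcns3 rose by 1.08 (SE 0.318). Of 23 vacuolar ATPase genes 7 fell, with a median of -0.39 and camera adjusted p = 0.449. Under median-ratio scaling 1 fell, with a median of 0.02, camera direction up and adjusted p = 0.538. With quantile normalization 4 fell, with a median of -0.40, camera direction down and adjusted p = 0.00763. Without scaling, camera gave adjusted p = 0.0024 for the zinc finger family, 0.132 for Wnt, 0.449 for homeobox and 0.521 for potassium channel genes. For the zinc finger family camera gave adjusted p = 0.000122 with median-ratio scaling and 0.07 with quantile normalization. With an estimated correlation no family was called, the adjusted p being 0.69 for the GTPase, proteasome and cytosolic ribosomal families and 0.815 for the others.

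Macrophage and endothelial marker means moved together between libraries of an LPS sample, with a slope of 0.893 (SE 0.204). The macrophage marker mean was 2.88 in LPS 1, 2.35 in LPS 2 and 2.30 in LPS 3, and the interferon-stimulated mean was 6.28, 7.38 and 7.74 (log2). In Vehicle 1, Mx1 stood at 15.4 TPM, against 0.377 TPM in Vehicle 2 and 1.39 TPM in Vehicle 3.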
